A study of Mus musculus with 6 samples.

How the data were processed

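Bulk RNA was measured in 6 HCA-1 liver tumors, 3 from untreated mice and 3 from mice given the BPRCX807-loaded nanoparticle. Per the labels' protocols, RNA was extracted with an RNeasy kit, its integrity was assessed, and libraries were made with a KAPA mRNA HyperPrep kit. Per the submitters' processing notes, the tools were CASAVA, FastQC, MultiQC, Trimmomatic 0.38, HISAT2 2.1.0 and featureCounts 2.0.0; their order and settings are not given in the sources used here. The genome build and the strand setting of the counting are not given there either, so genes that overlap on opposite strands cannot be separated and are reported as uncertain, as are near-identical family members.

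The authors deposited a table of whole-number read counts per gene, 1 column per library, with no normalization, for 55536 gene identifiers. All 55536 are in the GENCODE M21 annotation of the primary GRCm38 assembly, from which symbols and coordinates were taken. The authors also deposited a normalized signal table, which per the file headers and values has the same 6 libraries, with 36670 genes. Each normalized value was the count divided by 1 constant per library, with a largest relative deviation of 5.4e-10, and 0 of the 18866 genes left out of it had any count. Those constants were 1.11 to 1.12 times the DESeq2 size factors recomputed on the 6 libraries. The normalized table held 25 symbols that look like dates, so genes were matched by identifier.

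The main test was edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors, a filter for low counts (a count of at least 10 scaled by depth and a total of at least 15), robust quasi-likelihood dispersion and Benjamini-Hochberg adjustment over 16586 genes at 0.05. All 6 libraries entered with the group as the only term. CPM values are scaled by TMM factors, except those called unscaled, which are counts over the total count. Log2 fold changes are treated minus untreated, and errors are the SD over 3 libraries or the SE of the fit. The median log2 fold change of all tested genes was -0.06 and moved by less than 0.1 in every alternative fit. Adjusted p-values of single genes are from edgeR where no other tool is named.

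Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, for lists with at least 5 tested members, adjusted by Benjamini-Hochberg over 47 lists. The same lists were tested with a correlation estimated per list and with fry. A count adjusted over the list alone takes the edgeR p-values of the members and adjusts them within the list. In lists simulated with a correlation of 0.3 between members and no change, the preset correlation called 12.2 of 47 lists on average over 20 simulations, and the estimated correlation and fry called 0; a shifted list of independent genes was recovered with the preset correlation, and recovery with the other 2 tests was not simulated.

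The fits were tested on simulated data for the comparison of treated with untreated tumors, with 200 of the genes changed. On 16271 simulated genes, edgeR recovered 4 of 100 genes changed 2 times and 84 of 100 changed 4 times, with 98 calls of which 10 were false. DESeq2 1.42.0 on 16586 genes recovered 27 and 89, with 173 calls of which 57 were false, and limma-voom on 16271 genes recovered 2 and 81, with 93 calls of which 10 were false.

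Genes were named by a fixed rule. It took the 8 genes per direction with the largest change past the threshold, above 1 log2 CPM and without overlap between groups, places left being filled by the smallest unadjusted p; Cxcr4, Cxcl12 and Ackr3; the 3 members with the smallest p in the direction of each of the 10 lists camera ranked highest; and the 2 members with the smallest p of the T cell, CD8 and NK, macrophage, fibroblast and hepatocyte lists. Predicted genes and pseudogenes were passed over in the first part. A gene that the rule takes is not reported here.

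The alternatives were DESeq2, limma-voom with sample quality weights, limma-trend on log2 of the deposited normalized values plus 1, RLE and upper-quartile factors, no filter on low counts, a filter at 1 CPM in 3 libraries, dispersion without robust estimation, the mean level of the hepatocyte list as a covariate, factors without the hepatocyte, cytochrome P450 and acute phase lists, a block on the shared numbers, thresholds of 0.1 and of 2-fold, and leaving out each library. A limma-voom fit with a weight per group and the list member counts under each setting were added after seeing the data. No 2 libraries were duplicates, since counts of each pair differed by at least 22.2 times the sampling noise (chi-square per degree of freedom). No library was left out of the main results. Exact intervals given for ratios of counts cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.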

Results

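RNA was sequenced from liver tumors of C3H mice, grown from HCA-1 cells, a mouse hepatocellular carcinoma line, after the cells were placed under the liver capsule. The 3 treated tumors came from mice that received nanoparticles carrying BPRCX807, which the labels name as an inhibitor of the chemokine receptor CXCR4, into a vein on days 15, 16 and 17. The 3 control tumors were untreated, and no group given an empty nanoparticle was analysed here. All tumors were taken on day 17. The libraries are called untreated 1, 4 and 5 and TA807NP 1, 3 and 5, after their labels. The labels do not say which mouse each tumor came from, so the p-values measure the spread between these 6 tumor samples.

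The deposited counts summed to 20843690, 22489285 and 16883911 in untreated 1, 4 and 5 and to 20915036, 25129543 and 23505212 in TA807NP 1, 3 and 5. Between 24267 and 25969 genes had at least 1 count in a library. The treated tumors resembled each other closely, with Pearson correlations of log2 CPM across genes of 0.98 to 0.985 between pairs, whereas pairs of untreated tumors gave 0.919 to 0.957; these are correlations across genes, which are not independent replicates. Transcripts of 25 hepatocyte genes such as albumin took 1.38%, 4.71% and 0.653% of the counts in untreated 1, 4 and 5, against 1.81%, 1.54% and 1.10% in TA807NP 1, 3 and 5. Untreated 4 and untreated 5 therefore held the highest and the lowest share of liver transcripts of the 6 libraries, and they lay at opposite ends of the first principal component, which took 47.6% of the variance. Genes of the mitochondrial genome took 1.37% of counts in untreated 5 and 4.19% in untreated 4.

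**Figure D1:**
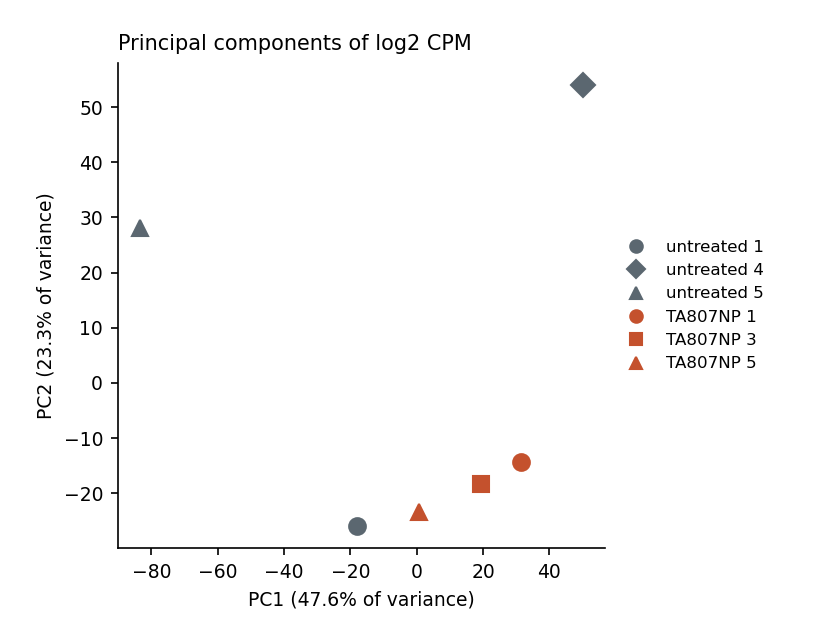
Scores of the 6 libraries on the first (x axis, 47.6% of variance) and second (y axis, 23.3%) principal components of log2 CPM, in arbitrary units, with untreated tumors in grey, treated tumors in orange and the shape giving the number in the label. The treated libraries lie between 0.782 and 31.3 on the x axis, while untreated 5 lies at -83.5 and untreated 4 at 50.02.

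The single comparison of the study asks how the nanoparticle treatment changed the transcriptome of the tumor. Transcripts of interferon-stimulated genes, of cytotoxic lymphocytes, of immune checkpoints and of MHC class I antigen presentation were higher in treated tumors as lists, with median log2 fold changes of 0.55 to 1.22 over their members. These calls used a preset correlation between genes and were lost with an estimated one (adjusted p = 0.216 with an estimated correlation for each) and with fry. The list of mast cells, basophils and eosinophils and the list of fibroblasts and collagen matrix were called higher with the preset correlation as well, with adjusted p = 0.235 and 0.216 with an estimated correlation. The erythroid list was lower, with summed unscaled CPM of 3 hemoglobin genes at 0.261 of the untreated level, and endothelial genes were lower by a small margin, with a median log2 fold change of -0.37; these had adjusted p = 0.216 and 0.573 with an estimated correlation. Cxcr4 itself had a mean of 25.6 ± 5.34 CPM (SD, n = 3) in untreated and 49.2 ± 4.04 CPM (SD, n = 3) in treated tumors. Except for that on Cxcr4, which had adjusted p = 0.197 in edgeR, these statements rest on lists of genes. No single gene passed the edgeR test over all genes.

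With edgeR's quasi-likelihood test on 16586 genes, 0 genes were higher and 0 were lower in treated tumors at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 1200 genes, 897 of them higher and 303 lower. The groups did not overlap in CPM for 2118 genes, 12.8% of those tested, where chance gives 10%. The smallest adjusted p in edgeR was 0.0727, for Myom1. DESeq2 called 233 genes higher and 13 lower, limma-voom with quality weights 0 and 0, with 1269 genes at an unadjusted p under 0.05, and limma on the deposited normalized values 0 and 0, with 1198 such genes. The edgeR count also changed to 184 higher and 2 lower without a filter on low counts, to 231 and 15 with the hepatocyte level of each library as a covariate, and to 106 and 3 without untreated 4. Of the 228 genes that DESeq2 called higher and edgeR tested, 228 had an unadjusted p under 0.05 in edgeR. Both tools used the same counts, so this is no independent support for the calls. In the simulated data 57 of 173 DESeq2 calls were false. Of 48 gene lists chosen before the data were examined, 47 had enough tested members, and limma's camera with a preset correlation of 0.01 between genes placed 21 of them higher and 3 lower in treated tumors. None of the 24 was called with a correlation estimated from these libraries or with fry, which tests the members alone, where the smallest adjusted p was 0.216 and 0.0547. List members named below beyond the fixed rule for named genes were chosen after their values were seen.

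**Figure D2:**
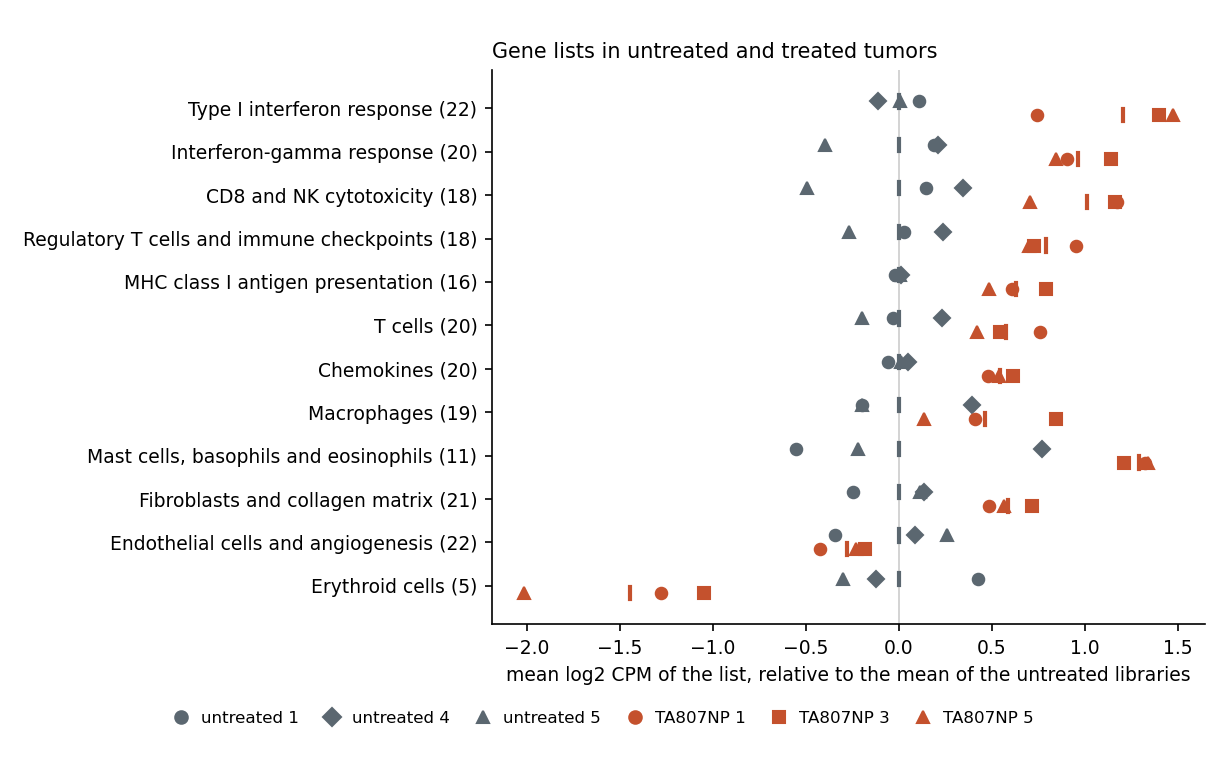
Mean log2 CPM of 12 gene lists in each library, relative to the mean of the untreated libraries (x axis, log2 units), with the number of members tested in brackets, untreated tumors in grey, treated tumors in orange, vertical bars for the means of 3 libraries and the shape giving the number in the label. The Type I interferon list lies between 0.74 and 1.47 in treated tumors and between -0.11 and 0.11 in untreated tumors, and the erythroid list lies between -2.01 and -1.05 in treated tumors.

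The Type I interferon list gave the smallest p of all lists in camera with the preset correlation, and the chemokine list with an estimated correlation and with fry. Of its 22 members, which include genes that cells switch on against viruses, 21 were higher in treated tumors at an edgeR p adjusted over the list alone, and all 22 had a positive log2 fold change, with a median of 1.22. Oas3, an enzyme that senses double-stranded RNA (ENSMUSG00000032661, chromosome 5, 120753098 to 120777661, minus strand), went from 15.7 ± 3.69 to 54.0 ± 11.2 CPM (SD, n = 3 each), a log2 fold change of 1.78 ± 0.25 (SE). Zbp1, a sensor of nucleic acids in Z form, had a log2 fold change of 1.44 ± 0.22 (SE), and Oasl2 had 62.6 ± 4.12 and 144 ± 32.4 CPM (SD, n = 3 each). Oasl1 was the member that did not pass, with a log2 fold change of 0.38. Of 20 genes of the interferon-gamma response, 19 were higher in treated tumors by the same test, with a median log2 fold change of 0.92. Among them Gbp2, a GTPase that acts on intracellular pathogens, had a log2 fold change of 1.21 ± 0.21 (SE), the GTPase Igtp 1.08 ± 0.20, and Cd274, which encodes the checkpoint ligand PD-L1, 1.25 ± 0.23. Guanylate-binding proteins are a family of similar genes, so reads may be split among Gbp2 and its relatives. Camera gave adjusted p = 2.24e-26 for the Type I list and 1.63e-21 for the interferon-gamma list, and adjusted p = 0.216 with an estimated correlation for each. Without TA807NP 3 the interferon-gamma count was 5 in place of 19, and limma-voom with quality weights counted 11 Type I genes in place of 21.

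All 18 tested genes of CD8 T cells and natural killer cells had a positive log2 fold change, with a median of 1.00, and 10 of them passed adjusted over the list alone in edgeR. The list was called by camera with the preset correlation, with adjusted p = 0.216 with an estimated correlation. Gzmb, which encodes granzyme B, a protease that kills target cells, had 6.99 ± 2.52 CPM in untreated and 24.3 ± 10.8 CPM in treated tumors (SD, n = 3 each), with a log2 fold change of 1.80 ± 0.39 (SE). Cd8a, a co-receptor of cytotoxic T cells, had 18.4 ± 7.14 and 46.6 ± 2.56 CPM, and the granule gene Nkg7 15.4 ± 3.26 and 30.8 ± 3.68 CPM. Of 20 T cell genes, 8 were higher adjusted over the list alone, among them Cd3e, Cd3d and Cd247 of the T cell receptor complex, with log2 fold changes of 1.00 ± 0.20, 0.96 ± 0.23 and 1.21 ± 0.25 (SE). Cd4 was at -0.01 and Tcf7 at -0.34 in the same list. In the list of regulatory T cell and checkpoint genes 12 of 18 passed, including Pdcd1 (log2 fold change 1.18), Lag3 (0.92 ± 0.19, SE) and Tnfrsf18 (1.11 ± 0.24). Foxp3, which defines regulatory T cells, did not pass and had 0.31. Camera called the 3 lists at adjusted p = 3.48e-13, 1.67e-08 and 5.07e-13, with adjusted p = 0.216, 0.235 and 0.216 with an estimated correlation.

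These counts fell without some libraries and rose without others. Without untreated 4 the cytotoxic, T cell and checkpoint counts were 13, 9 and 13. Without TA807NP 5 the T cell count was 10, and the cytotoxic and checkpoint counts were 8 each. The cytotoxic count was 6 without untreated 1, 5 without TA807NP 1 and 0 without TA807NP 3, where 7 members kept an unadjusted p under 0.05 in edgeR; DESeq2 on all 6 libraries counted 13. The T cell count was 4 without untreated 1 and 0 without TA807NP 1 or TA807NP 3, where 7 and 8 members had an unadjusted p under 0.05; DESeq2 on all 6 libraries counted 8. For the checkpoint list 3 genes passed without TA807NP 1 and 5 without TA807NP 3. With the preset correlation, camera called all 3 lists whichever library was left out, with adjusted p of at most 2.2e-05. The estimated correlation and fry were not run with a library left out.

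All 16 tested genes of MHC class I antigen presentation had positive log2 fold changes, with a median of 0.55, and 8 passed adjusted over the list alone. Tapbp and Tap1, of the class I peptide-loading pathway, had 200 ± 27.6 and 131 ± 13.3 CPM in untreated tumors and 413 ± 64.7 and 234 ± 23.3 CPM in treated tumors (SD, n = 3 each). H2-T23, a non-classical class I gene, had a log2 fold change of 0.85 ± 0.20 (SE) and its neighbor H2-T24 1.33 ± 0.18. The classical genes H2-K1 and H2-D1 had 0.58 and 0.49 and did not pass. Class I genes resemble each other and differ between mouse strains, so their separate counts are uncertain. The list had adjusted p = 3.71e-12 by camera, and adjusted p = 0.216 with an estimated correlation. The count of 8 was 5 without untreated 1, 5 without untreated 4, and 0 without TA807NP 1 or TA807NP 3, where 5 and 6 members had an unadjusted p under 0.05 in edgeR, and 13 with the hepatocyte covariate; DESeq2 on all libraries counted 9.

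Among 20 chemokine genes 4 passed adjusted over the list alone, all of them higher. Ccl2, which draws monocytes, had 35.3 ± 3.77 and 69.9 ± 9.18 CPM, Ccl8 94.3 ± 41.0 and 321 ± 83.2 CPM, and Cxcl10, which draws activated T cells, 14.8 ± 1.98 and 33.3 ± 7.77 CPM in untreated and treated tumors (SD, n = 3 each); the fourth gene was Ccl7. The chemokine list had adjusted p = 2.88e-07 by camera, and adjusted p = 0.216 with an estimated correlation. The chemokine count was 7 without untreated 4, 8 with DESeq2, 7 with limma-voom, 10 without a filter on low counts and 9 with the hepatocyte covariate. Of 19 macrophage genes 14 had a positive log2 fold change and the median was 0.63. The lysosomal protease Ctss had a log2 fold change of 1.08 ± 0.27 (SE) and the lysozyme gene Lyz2 0.93 ± 0.28, while Clec4f, a marker of resident liver macrophages, had -0.93. Camera called the macrophage list at adjusted p = 4.26e-06, with adjusted p = 0.48 with an estimated correlation. In edgeR 0 macrophage genes passed adjusted over the list alone and 11 had an unadjusted p under 0.05. The counts were 12 without untreated 4, 10 without TA807NP 5, 8 with DESeq2, 7 with limma-voom, 4 with limma on the normalized values, 9 without a filter on low counts and 11 with the hepatocyte covariate. Both activation lists for macrophages were called higher by camera, the M1-type list with 2 of 16 members passing (Cxcl10 and Nos2) at adjusted p = 4.32e-05 and the M2-type list at 0.00219, with adjusted p = 0.233 and 0.216 with an estimated correlation. The M1-type count of 2 was 0 without untreated 1, where 4 members had an unadjusted p under 0.05 in edgeR, 0 without TA807NP 3, where 2 did, and 1 without untreated 5. It was 4 without untreated 4 or TA807NP 5, 5 without a filter on low counts or with the hepatocyte covariate, 2 with DESeq2 and 1 with limma-voom. In the M2-type list 0 of 20 members passed in edgeR, 7 had an unadjusted p under 0.05, DESeq2, limma-voom and limma-trend counted 6 each, and 8 passed without untreated 4, 7 without a filter on low counts and 8 with the hepatocyte covariate.

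In a list of 11 tested genes of mast cells, basophils and eosinophils, 8 passed adjusted over the list alone and all 8 are genes that mast cells express: Tpsb2, Fcer1a, Kit, Hdc, Ms4a2, Cpa3, Cma1 and Mcpt4. Tpsb2, a mast cell tryptase, had 22.2 ± 11.7 CPM in untreated and 78.1 ± 22.3 CPM in treated tumors (SD, n = 3 each), a log2 fold change of 1.81 ± 0.39 (SE), and its near copy Tpsab1 may share its reads. The high-affinity IgE receptor chain Fcer1a had 0.475 ± 0.169 and 2.47 ± 1.26 CPM, and Kit, the receptor for stem cell factor, 13.4 ± 2.03 and 25.5 ± 4.63 CPM. The eosinophil and basophil genes Ear2, Siglecf and Mcpt8 did not pass, with log2 fold changes of -0.69, 0.52 and 0.12. The list had adjusted p = 1.11e-08 by camera, and adjusted p = 0.235 with an estimated correlation.

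Of 21 genes of fibroblasts and collagen matrix, 10 were higher in treated tumors adjusted over the list alone. Lox, which cross-links collagen (chromosome 18, 52516067 to 52529867, minus strand), had 47.7 ± 14.2 and 140 ± 12.1 CPM (SD, n = 3 each), a log2 fold change of 1.55 ± 0.25 (SE). The microfibril gene Fbn1 had 0.92 ± 0.16 and Thy1 0.95 ± 0.18. Col3a1, Col5a1 and Col5a2 passed as well, while Col6a1 and Col6a2 had -0.50 and -0.39 and the fibroblast markers Fap and Pdgfrb -0.03 and -0.05. Fibroblast genes as a list had adjusted p = 7.63e-11 by camera, and adjusted p = 0.216 with an estimated correlation, and the count was 6 without TA807NP 3. Mesothelial genes were called higher too, at adjusted p = 0.000703 by camera and adjusted p = 0.434 with an estimated correlation, with Wt1 (log2 fold change 1.63) and Msln (1.05) passing among 8; this count was 1 without untreated 1, untreated 5 or TA807NP 3 and 1 with limma-voom, and the list mean relative to the untreated mean was 1.89 in TA807NP 3 against 0.35 and 0.62 in TA807NP 1 and 5. Of 16 targets of the oxidative stress factor NRF2, 4 passed and were higher, Gsta1 (2.27), Hmox1 (1.07), Abcc4 (0.82) and Srxn1 (0.67), at camera adjusted p = 4.69e-06 and adjusted p = 0.216 with an estimated correlation; this count was 2 without TA807NP 1 and 1 without TA807NP 3.

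Of 5 erythroid genes tested, 4 passed adjusted over the list alone, namely Hba-a1, Hbb-bs, Hbb-bt and Bpgm, with log2 fold changes of -2.19, -1.94, -2.22 and -0.42, and Alas2 had -1.03. The alpha-globin gene Hba-a1 (ENSMUSG00000069919, chromosome 11, 32283511 to 32284465, plus strand) had 94.3 ± 42.1 CPM in untreated and 20.7 ± 8.00 CPM in treated tumors (SD, n = 3 each), and its near-identical copy Hba-a2 may take part of its reads. Camera gave adjusted p = 7.68e-06, and adjusted p = 0.216 with an estimated correlation. The count of 4 was 1 without TA807NP 1, and 0 without a filter on low counts, where 12 members enter the list and 4 had an unadjusted p under 0.05 in edgeR; DESeq2 called the 3 globin genes over all genes and counted 4 over the list. Endothelial genes had a median log2 fold change of -0.37 and were negative in 18 of 22 members, with Erg, a transcription factor of endothelial cells, at -0.89 ± 0.23 (SE) and Flt1 at 0.64. Camera called them lower at adjusted p = 0.002, with adjusted p = 0.573 with an estimated correlation; 0 members passed in edgeR adjusted over the list alone, 4 had an unadjusted p under 0.05, DESeq2 counted 1, limma-voom and limma-trend 0 each, and 6 passed without untreated 1, 1 without untreated 5, 1 without a filter on low counts and 1 with the hepatocyte covariate.

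The transcript of the receptor named as the drug's target was measured, and not its protein. Cxcr4 (ENSMUSG00000045382, chromosome 1, 128588199 to 128592293, minus strand) had a log2 fold change of 0.94 ± 0.20 (SE), higher in all 3 treated than in all 3 untreated tumors, with adjusted p = 0.197 over all genes in edgeR. It passed with DESeq2 (log2 fold change 0.95, adjusted p = 0.0254), without a filter on low counts (0.98, adjusted p = 0.0188) and with the hepatocyte covariate (0.96, adjusted p = 0.0294); the adjusted p ranged from 0.0188 to 0.882 over all settings tried. Ackr3, which encodes the other receptor of the ligand CXCL12, had 22.7 ± 3.95 and 56.9 ± 6.57 CPM (SD, n = 3 each), a log2 fold change of 1.32 ± 0.20 (SE) and adjusted p = 0.163 in edgeR. It passed with DESeq2 (adjusted p = 0.000164), and in edgeR without a filter on low counts, with the hepatocyte covariate and without untreated 4. Its adjusted p ranged from 0.000164 to 0.807 over all settings tried. Cxcl12 itself varied from 31.7 to 213 CPM among untreated tumors and had a log2 fold change of 0.14 ± 0.70 (SE), which became -0.11 without untreated 1, -0.28 without untreated 5, -0.07 without TA807NP 3, 0.34 without TA807NP 5 and 1.27 without untreated 4, at adjusted p = 0.133 in edgeR or higher in each. It passed in no setting outside the block. The list of 9 genes of this axis was called higher by camera at adjusted p = 0.0435, with adjusted p = 0.333 with an estimated correlation. In edgeR 2 members, Cxcr4 and Ackr3, passed adjusted over the list alone, and 4 without untreated 4. That camera call was lost without untreated 1 (adjusted p = 0.314), TA807NP 1 (0.0587) or TA807NP 3 (0.124), and with a filter at 1 CPM in 3 libraries (0.0518).

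**Figure D3:**
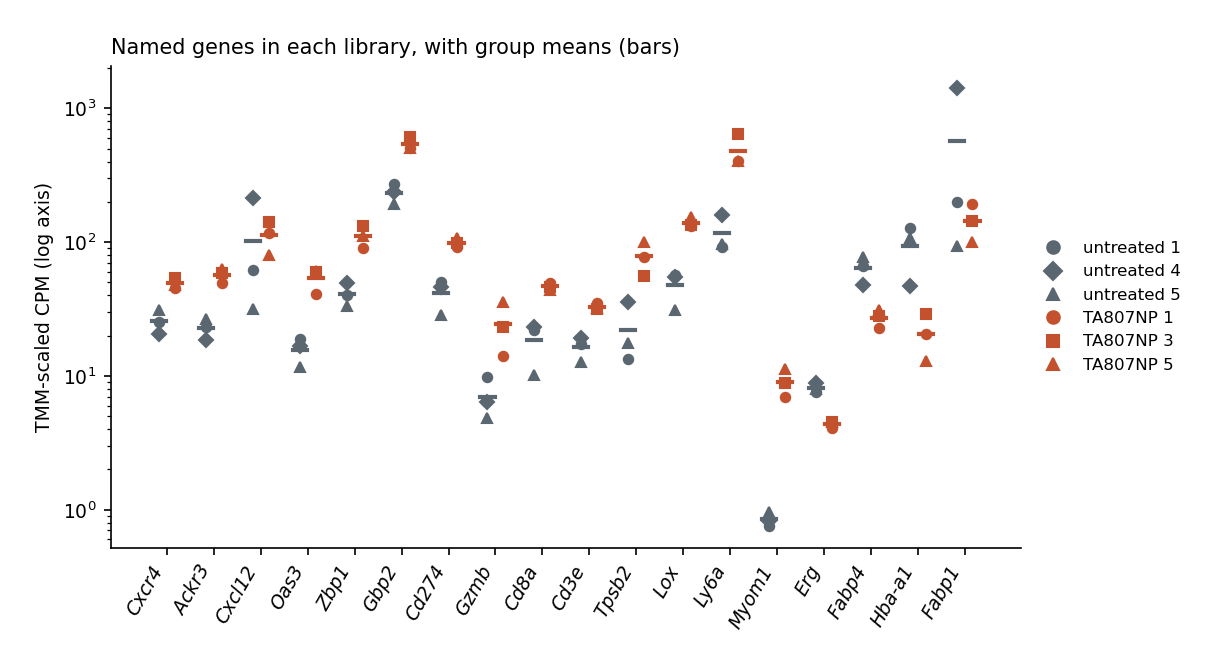
TMM-scaled CPM (y axis, log scale) of 18 named genes in each library, with untreated tumors in grey, treated tumors in orange, horizontal bars for the means of 3 libraries and the shape giving the number in the label. Myom1 lies between 6.94 and 11.3 CPM in treated tumors and at or below 0.964 CPM in untreated tumors, and Fabp1 reaches 1420 CPM in untreated 4.

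Among single genes ranked by p, Myom1, which encodes a protein of the muscle sarcomere, stood apart. It lies on chromosome 17 from 71002633 to 71126856 (ENSMUSG00000024049, plus strand) and shares 246 bases with Myl12a on the other strand. Its level was 0.848 ± 0.105 CPM in untreated and 9.05 ± 2.17 CPM in treated tumors (SD, n = 3 each), a log2 fold change of 3.41 ± 0.32 (SE) with adjusted p = 0.0727 in edgeR. The next genes in order were Vldlr, a lipoprotein receptor, with 5.24 ± 0.136 and 14.9 ± 0.542 CPM, H2-T24, the scavenger receptor gene Ssc5d (log2 fold change 1.28), Pdpn, which encodes podoplanin (1.32), Oas3, the phospholipase gene Pla1a (1.28) and Ly6a, which encodes Sca-1 and has many close relatives (2.05); each had adjusted p = 0.163. Among genes lower in treated tumors, Fabp4, a fatty acid carrier of fat cells and capillary endothelium, went from 63.7 ± 14.8 to 27.3 ± 4.05 CPM, followed by Hba-a1, the Notch target Heyl (-1.16), the noncoding RNA Rn7sk (-0.87), Btnl9 (-1.26), Erg, Bdh2 (-0.84) and Trp53i11 (-1.34), with adjusted p of 0.194 to 0.32. None of these 16 passed in edgeR over all genes, while DESeq2 called all of them except Rn7sk, Erg and Bdh2. In edgeR the 8 higher genes and Fabp4 passed without untreated 4, without a filter on low counts and with the hepatocyte covariate. Hba-a1 passed without untreated 4 and with the covariate, and Trp53i11 without the filter and with the covariate.

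Liver and tumor cell lists were not called in the main camera test with all 6 libraries. The 25 hepatocyte genes had a median log2 fold change of -0.71 with adjusted p = 0.669 by camera, but the list was called higher without untreated 4 (adjusted p = 4.94e-07) and lower without untreated 5 (9.98e-07). Fabp1 ranged from 93.7 to 1420 CPM within the untreated tumors, with a log2 fold change of -1.98 ± 1.03 (SE), which was -0.02 without untreated 4 and passed only with the hepatocyte covariate among the settings outside the block (-1.10, adjusted p = 0.024 in edgeR, range 0.024 to 0.999). The covariate is the mean level of the hepatocyte list, which includes Fabp1, so that call is not independent of the gene itself. Trf had -0.93 ± 0.45. Cytochrome P450 and acute phase genes had edgeR medians of -0.36 and -0.37 but a camera direction upwards, at adjusted p = 0.0828 and 0.604. The edgeR values rest on counts and camera on log2 CPM, where 1 high library weighs less. In log2 CPM relative to the untreated mean, the P450 list had -0.60, 2.21 and -1.61 in untreated 1, 4 and 5. The same list had 1.12, 0.39 and 0.25 in TA807NP 1, 3 and 5. The acute phase list was called higher without untreated 4 (0.0485) and lower without untreated 5 (1.93e-08), and the cytochrome P450 list higher without untreated 4 (4.14e-11), without TA807NP 5 (0.0214) and with the hepatocyte covariate (0.00233). With all 6 libraries, median and camera direction also differed in sign, without a call, for sinusoidal and lymphatic endothelial, cholesterol synthesis, dendritic cell, NF-kB and Wnt and Hippo lists, and mean and median for neutrophil and NF-kB genes. Cholesterol synthesis was called higher without untreated 4 (0.00258) or TA807NP 5 (0.0285) and lower without untreated 5 (0.0316). Sinusoidal endothelial genes were called higher without untreated 4 (0.0207), NF-kB genes without untreated 5 (0.0101), and neutrophil genes without untreated 5 (0.0186), TA807NP 1 (0.0023) or TA807NP 5 (0.0334). Cell cycle genes had medians of 0.09 for G2/M and 0.11 for S phase (adjusted p = 0.125 and 0.197), genes of the epithelial-mesenchymal transition 0.15 (0.0889), p53 targets -0.23 (0.261) and stellate cell genes 0.31 (0.0527). Camera called both cell cycle lists higher without untreated 1 (0.0022 and 0.0153) or TA807NP 5 (0.00427 and 0.031), the transition list without untreated 5 (0.0123), TA807NP 1 (0.0367) or TA807NP 3 (0.0458), and p53 targets lower without untreated 4 (0.0224). Stellate cell genes were called higher without untreated 4 (0.0224), untreated 5 (0.00295), TA807NP 1 (0.00139) or TA807NP 5 (0.0334), with RLE factors (0.0475) and with the hepatocyte covariate (0.0433).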

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

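The limma-voom fit with a weight per group and the counts of list members by setting were chosen only after the results were seen. Counts of genes higher and lower in treated tumors were 0 and 0 in edgeR, with 1200 genes at an unadjusted p under 0.05, and moved to 233 and 13 with DESeq2, 184 and 2 without a filter on low counts, 231 and 15 with the hepatocyte covariate, 1 and 0 at an adjusted p under 0.1, and from 0 to 106 and 0 to 3 when a library was left out, the upper values being without untreated 4; the cause was not tested. Of the genes DESeq2 called higher, 166 were also called without the filter, 156 with the covariate and 66 without untreated 4. Both counts stayed at 0 with limma-voom (1269 genes at an unadjusted p under 0.05), limma-trend (1198), RLE (1197) and upper-quartile factors (1185), the 1 CPM filter (1079), no robust estimation (1203) and a weight per group (1032). Cxcr4 passed with DESeq2 (log2 fold change 0.95), without the filter (0.98) and with the covariate (0.96), and kept its sign in all 18 settings; the cause was not tested. Cxcl12 ranged from -0.28 to 1.27 with a library left out, with -0.11 without untreated 1 and -0.07 without TA807NP 3; the cause was not tested. Lists called higher and lower, 21 and 3, became 0 and 0 with an estimated correlation and 0 and 0 with fry, and ranged from 18 to 27 and from 2 to 6 with a library left out; the cause was not tested. RLE factors gave 22 and 3, the 1 CPM filter 18 and 3 and the covariate 23 and 3; 24, 21 and 24 of the 24 called lists were called there in the same direction, and 0 turned. The other values pool log2 fold changes of named genes with counts of list members, and 1037 of them were unchanged. For a gene this means that it still did not pass and kept its sign, and for a count that it stayed near the main count. Gene values that passed only under the alternative were 160, and 95 counts moved. In 4 cases a gene reversed, namely Cxcl12 in 3 settings and Fabp1 in 1, given here. No named gene passed in the main fit, so an unchanged gene is no sign of a stable call. With 3 libraries per group, simulated 2-fold changes were mostly missed by edgeR (4 of 100 recovered). The labels do not say that a shared number marks a shared animal, so the numbers were not taken as pairs. Libraries with the same number deviated from their group means with correlations of -0.0144 (number 1) and 0.317 (number 5). Libraries of different groups with unlike numbers gave -0.39 to 0.39, so these values cannot show or exclude pairing. A replicate block on numbers 1 and 5, which keeps 4 libraries, gave 892 genes higher and 168 lower, and 18 lists higher and 7 lower. It also gave a Cxcl12 call (adjusted p = 0.00431 in edgeR) and a Fabp1 log2 fold change of 0.0357 in place of -1.98. The cause was not tested, and the fit leaves out untreated 4 and TA807NP 3. It keeps 1 residual degree of freedom, so its p-values rest mainly on the spread shared across genes. Its counts are therefore no measure of what pairing would show.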

Other observations

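The tests of admixed liver, blood, vessels, muscle and the overlapping gene were chosen only after the results were seen.

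Other gene groups fixed in advance were also called by camera with the preset correlation, and none of these calls held with an estimated one. Of 21 hypoxia and glycolysis genes, 18 had a positive log2 fold change, with a median of 0.32, and 2 passed adjusted over the list alone in edgeR, the phosphofructokinase gene Pfkp (0.61 ± 0.15, SE) and Pfkfb3 (0.76 ± 0.18), a regulator of glycolysis. The list had adjusted p = 0.000207 by camera, with adjusted p = 0.577 with an estimated correlation; without untreated 4 the call was lost (0.679), and in each fit without a library 0 members passed in edgeR, 2 to 8 having an unadjusted p under 0.05, while DESeq2 and limma-voom on all 6 counted 2. The 12 heat shock genes were all negative, with a median of -0.32 and Hspb1 at -1.14 ± 0.59 (SE), at camera adjusted p = 0.0325 and adjusted p = 0.69 with an estimated correlation. That call was lost without untreated 1 (0.316), untreated 5 (0.559) or TA807NP 3 (0.103), and 0 members passed in edgeR adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 by DESeq2 and limma-voom, and 4 without untreated 4. In the list for DNA sensing by cGAS and STING, Zbp1 passed and Tmem173, which encodes STING, had 0.76 ± 0.26 (SE), at adjusted p = 0.0034 and adjusted p = 0.216 with an estimated correlation; the count of 1 was 3 without untreated 4 and 2 without TA807NP 5, without a filter on low counts or with the hepatocyte covariate.

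Of 12 MHC class II genes, 10 were positive, with a median log2 fold change of 0.54 and H2-Aa at 806 ± 153 and 1178 ± 456 CPM (SD, n = 3 each). Camera gave adjusted p = 0.00219, with adjusted p = 0.577 with an estimated correlation, lost without untreated 1 (0.0745) or TA807NP 1 (0.0967); 0 members passed in edgeR, 4 had an unadjusted p under 0.05, DESeq2 and limma-voom counted 0, and 6 passed without TA807NP 5 and 5 without a filter on low counts. B cell and plasma cell genes had a median of 0.35 at adjusted p = 0.0448 and adjusted p = 0.719 with an estimated correlation, lost without untreated 1 (0.855) or TA807NP 1 (0.531). In that list 0 members passed in edgeR, 0 had an unadjusted p under 0.05, DESeq2 and limma-voom counted 0, and 4 passed without untreated 4 and 3 with the hepatocyte covariate. By unscaled CPM, summed immunoglobulin genes had 161, 979 and 156 CPM in untreated 1, 4 and 5 and 1571, 596 and 586 CPM in TA807NP 1, 3 and 5. Summed T cell receptor genes had 103, 92.3 and 107 unscaled CPM in untreated and 138, 157 and 129 CPM in treated tumors, in the same order.

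Interferon, T cell and MHC class I lists were called higher in treated tumors with a preset correlation, and none with fry or with an estimated correlation (adjusted p = 0.216 to 0.235 with an estimated correlation); the median log2 fold change over the 113 members of 6 lists was 0.898. Removing a trend on GC content and transcript length left 0.971 (bootstrap interval over genes 0.849 to 1.03), which argues against such a trend as the whole cause. The hepatocyte level of each library as a covariate left 0.918 (0.833 to 0.995). Relative to the mean of all 6 libraries, that level was -0.34, 1.90 and -1.57 in untreated 1, 4 and 5. It was 0.31, 0.004 and -0.30 in TA807NP 1, 3 and 5. Its group means hardly differed, so the covariate could not move the fold much and is no test of liver content as a cause. Both intervals resample genes that vary together and carry no spread between tumors. A larger number of leukocytes stays open for the Type I interferon list. Its mean minus that of 15 leukocyte genes differed between groups by 0.702, within 2 times the pooled SD of 0.51, and TA807NP 1 at 0.07 lay below untreated 1 at 0.24, although the leukocyte genes themselves differed by 0.50 and the interferon genes by 1.20. An effect of the treatment on interferon signalling or on the number of leukocytes, and an effect of the nanoparticle without the drug, were not separated by the design.

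Hemoglobin transcripts were lower in treated tumors, at 0.261 of the untreated unscaled CPM, a list call with adjusted p = 0.216 with an estimated correlation. Less blood in the tissue would lower platelet transcripts as well, but 8 platelet genes together had an unscaled CPM ratio of 1.25; Itga2b, which mast cells also express, made up 72.8% of those counts. Ppbp, Gp9 and Treml1 alone, chosen after this was seen, had 82 counts in treated and 95 in untreated tumors, a ratio of unscaled CPM of 0.747 (exact interval 0.549 to 1.01), which was 1.13 without untreated 1 and 0.627 to 0.821 without each of the other libraries, where the hemoglobin ratio was 0.355 without untreated 1 and 0.195 to 0.323 otherwise. The choice of Ppbp, Gp9 and Treml1 also left out Gp1ba, which had 23, 32 and 15 counts in untreated 1, 4 and 5. Its counts were 45, 27 and 47 in TA807NP 1, 3 and 5. The direction therefore depends on which platelet genes are taken, and they do not settle the amount of blood. A loss of vessels in proportion would need a similar fall of endothelial genes, whose median log2 fold change was -0.37 (bootstrap interval -0.48 to -0.21) against -2.19 for hemoglobin. That interval resamples genes and carries no spread between tumors. Other explanations, an effect of the treatment among them, were not tested.

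Myom1 was higher in each of the 3 treated tumors. Skeletal muscle in the tissue would bring its abundant transcripts, yet in 2 treated libraries 7 abundant muscle genes together stayed below Myom1, with 3.54 against 7.12 CPM in TA807NP 1 and 3.11 against 11.7 CPM in TA807NP 5, without TMM scaling. In TA807NP 3 the muscle genes reached 179 unscaled CPM. Reads from Myl12a, which overlaps Myom1 on the other strand, are also argued against by its log2 fold change of -0.0808 ± 0.184 (SE). Other explanations, an effect of the treatment among them, were not tested.

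The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. In edgeR the real split called 0 genes and the highest other split 0, so 10 of 10 splits called as many; the real split had 1200 genes at an unadjusted p under 0.05. Of the 10 splits, 3 had at least that number, the real one included. DESeq2 called 246 genes in the real split and 502 in the highest other, which set untreated 1, untreated 5 and TA807NP 5 against the rest, and 2 of 10 splits called as many as the real one. That split had 2470 genes at an unadjusted p under 0.05 in edgeR. It follows the hepatocyte level, which was lowest in those 3 libraries. The mean of the leukocyte genes was lowest in them too. Relative to the untreated mean it was -0.13, -0.20 and 0.18 there, against 0.33, 0.67 and 0.66 in untreated 4, TA807NP 1 and TA807NP 3. The split therefore does not tell liver content from leukocyte content, and what its calls rest on was not tested. Camera called 24 lists in the real split and 26 in the same other split, and 4 of 10 splits called at least 24.

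Xist, the RNA of the inactive X chromosome, had 10.03, 22.9 and 12.0 unscaled CPM in untreated 1, 4 and 5 and 75.3, 26.6 and 63.3 in TA807NP 1, 3 and 5, while the Y-linked gene Ddx3y had 93.3 to 148 unscaled CPM in all 6 and the labels describe male mice. The muscle actin gene Acta1 had 57.4 TMM-scaled CPM in TA807NP 3 and at most 0.615 in the other libraries, and camera called the 6 skeletal muscle genes higher at adjusted p = 0.00606 (adjusted p = 0.529 with an estimated correlation), lost without untreated 1 (0.0748) or TA807NP 3 (0.517). Platelet genes were called higher at adjusted p = 0.0236 (adjusted p = 0.241 with an estimated correlation), with Itgb3 the member that passed adjusted over the list alone (log2 fold change 0.95; 2 passed without untreated 4) and the call lost without untreated 1 (0.0803) or TA807NP 5 (0.0789). Of the 10 platelet genes in that list 5 were tested. The platelet genes Ppbp, Gp9 and Treml1 together, chosen after values were seen, had a ratio of unscaled CPM of 0.747 (exact interval 0.549 to 1.01), in the other direction. Gp1ba, left out of that choice, had more counts in TA807NP 1 and 5 than in any untreated library. The T cell receptor segment Trbv14 had 0, 0.0458 and 0 TMM-scaled CPM in untreated 1, 4 and 5 and 3.87, 1.51 and 2.05 CPM in TA807NP 1, 3 and 5.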
